A study of Homo sapiens with 18 samples.

How the data were processed

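RNA was measured by sequencing in 2 human breast cancer cell lines, MDA-MB-231 (estrogen receptor negative) and T47D (estrogen receptor positive), in which doxycycline switches on an introduced G0S2 gene. Per the labels, each line was taken without doxycycline (day 0, the control), and after 3 or 15 days of doxycycline at 0.5 ug/ml, with 3 libraries in each of the 6 groups and 18 libraries in all. Total RNA was isolated with a column kit and sequenced on an Illumina HiSeq instrument, per the labels. The series description speaks of biological triplicates, but of parental and Aza-resistant lines, which differ from the doxycycline groups in the sample labels; the labels were followed here. The sample labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical. No group of doxycycline-treated cells without the introduced gene was analysed here, so the effects of G0S2, of doxycycline and of the vector are confounded in every comparison.

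The deposited tables, one per cell line, hold log2 CPM (read counts scaled to library size) per gene and library; the unit was read from the values. Reads were aligned with STAR, counted with featureCounts and handled with limma on build GRCh38.p13, per the submitters' processing notes, which give no versions. The normalization step, the filter on low genes and the use of strand in counting are not given in the sources used here. Every deposited value corresponds to a whole number of reads within 0.1, once a pseudocount of 3 reads scaled to library size is removed, so the depth of each library was recovered: 37 to 52.4 M reads in MDA-MB-231 and 40.1 to 51 M in T47D. Scaling factors of the libraries lay between 0.991 and 1.004 in MDA-MB-231 and between 0.9917 and 1.012 in T47D, and their product was 1 within each table, which shows that the tables were normalized separately. The tables list 14308 genes (MDA-MB-231) and 14768 genes (T47D), 12666 of them in both, and all listed genes were tested. A log2 fold is on the scale of log2(CPM + pseudocount) and understates the change of genes with few reads. Reads of paralogs, pseudogenes and overlapping or antisense genes may be split or merged by the authors' counting; members of the HLA, IFIT, OAS, histone and ribosomal protein families are uncertain for that reason.

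The design was fixed before the data were examined, with one test written for whole-number counts and another for log2 values; since the tables hold log2 values, the second was used. For each line, limma 3.58.1 (R 4.3.3, with statmod 1.5.0) was fitted to the 9 libraries as deposited, with group means as the only terms and with trend and robust variance moderation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the table. Comparisons were day 3 against control, day 15 against control and day 15 against day 3. Because the tables were scaled separately, the design gave no test of the difference between lines; a fit over all 18 libraries, chosen after the data were seen, is given with the closing observations.

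In the same design, 34 gene lists were fixed, 6 of which mark other cells or RNA quality: replication-dependent histones, fibroblasts, leukocytes, endothelial cells, and the identity genes of either line. Each list was tested with limma's camera at its preset correlation of 0.01, adjusted over all lists and the 4 comparisons against control, and again with an estimated correlation; where a list is followed by a pair of p-values, they are in this order. Called members were counted over all genes and adjusted over the list alone. The mitochondrially encoded list had no listed member and was not analysed here; the share of reads on mitochondrial ribosomal RNA was 0.378% to 0.486% in every library. Endothelial markers were tested in MDA-MB-231 alone, which leaves 33 lists in MDA-MB-231 and 32 in T47D.

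Genes named in the text follow a rule fixed in advance. It takes G0S2; the 6 largest called rises and falls in each comparison against control, among genes with mean log2 CPM of 1 or more whose induced and control libraries do not overlap, without unnamed loci; up to 4 called members, by size of change, of each list that passed camera or had 3 or more called members; and a panel of 12 genes whatever their call (ESR1, PGR, TFF1, GREB1, GATA3, FOXA1, MYC, CCND1, VIM, CDH1, PNPLA2 and PLIN2). For the difference between lines it takes the 5 largest called differences in each direction. The rule gave more genes than the text prints: some of its genes are not reported here, and among list members preference went to those whose call held when each library was left out in turn.

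Whether libraries of a group were distinct was checked with a chi-square over genes with 10 or more reads in every pair of libraries; each pair differed by more than sampling noise, so each library was counted once. G0S2 coordinates come from GENCODE release 29 on GRCh38. GC content of transcripts of 200 bases or more, from the same annotation, was available for 92.4% of genes in MDA-MB-231 and 90.3% in T47D. Tables and plots were made with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

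The test was tried on simulated reads drawn around each gene's mean with the spread fitted between libraries, with 200 genes changed in each comparison, 50 at each of 4 folds. At folds of 1.2, 1.5, 2 and 4, the share recovered was 60%, 82%, 96% and 100% for MDA-MB-231 day 3 (14308 genes), 60%, 78%, 96% and 98% for MDA-MB-231 day 15, 48%, 82%, 96% and 100% for T47D day 3 (14768 genes) and 48%, 76%, 96% and 98% for T47D day 15. False calls made up 6.1%, 7.3%, 4.1% and 12.6% of the calls in the same order, above the nominal 5% except for T47D day 3. The fit over both lines (12666 genes) recovered 34%, 88%, 94% and 100% at day 3 and 36%, 86%, 94% and 100% at day 15, with 6% and 6.5% false calls, both above 5%.

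Alternatives fixed in advance were quantile normalization, limma without trend and robust moderation, a stricter filter on low genes, the replicate number as a block, only the libraries of the compared groups, a further 2-fold threshold, the estimated correlation for lists, and leaving out each library in turn. Added after the data were seen were voom on the recovered reads, a correction of each library for GC content, the omission of T47D day 15 replicate 2 from comparisons it is not part of, and list tests with each library left out.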

Results

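Gene expression was measured in 18 libraries of 2 breast cancer cell lines that carry a doxycycline-inducible G0S2 gene. MDA-MB-231 lacks the estrogen receptor and T47D has it. Each line gave 3 libraries without doxycycline (control), 3 after 3 days and 3 after 15 days of doxycycline at 0.5 ug/ml. Every value given for a group rests on n = 3 libraries, and SE is the standard error of a log2 fold in the fit over the 9 libraries of the line.

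G0S2 encodes a small protein known as an inhibitor of the triglyceride lipase PNPLA2. The gene (ENSG00000123689.5) lies on chromosome 1 of GRCh38, from 209675420 to 209676388 on the plus strand, and has 2 exons, with the coding sequence in exon 2 (209675685 to 209675993). In MDA-MB-231, G0S2 had 25.02 to 25.48 CPM in the control libraries, 1429 to 1506 CPM at day 3 and 1103 to 1294 CPM at day 15. In T47D it had 0.277 to 0.90 CPM in control libraries (14 to 40 reads), 844.3 to 882.7 CPM at day 3 and 735.9 to 992.8 CPM at day 15. On the log2 scale, G0S2 rose by 5.87 (SE 0.0459, adjusted p = 1.31e-14) at day 3 and 5.57 (SE 0.0459, adjusted p = 2.31e-14) at day 15 in MDA-MB-231, and by 10.67 (SE 0.371, adjusted p = 9.54e-06) and 10.61 (SE 0.371, adjusted p = 7.86e-06) in T47D. Reads are counted per gene, so introduced and endogenous transcripts are counted together. The T47D fold rests on few control reads and depends on the pseudocount of 3 reads.

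**Figure D1:**
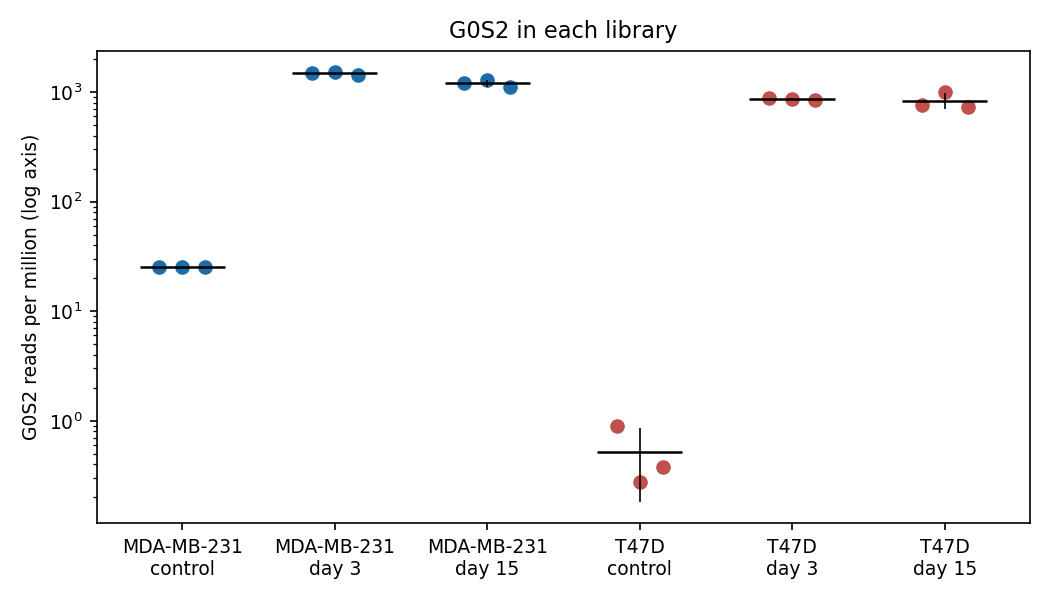
G0S2 in CPM (log axis) in each of the 18 libraries; points are libraries, horizontal lines group means and vertical lines SD, with n = 3 per group. Control libraries lie at 25.02 to 25.48 in MDA-MB-231 and under 0.90 in T47D, and all induced libraries at 735.9 or more.

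In MDA-MB-231, the comparison of day 3 with control asks how receptor-negative cells first respond to induction. Genes that make cholesterol and fatty acids rose together by small amounts. SCD, which encodes stearoyl-CoA desaturase, rose by a log2 fold of 0.35 (SE 0.0178), INSIG1, which holds the SREBP regulators in the endoplasmic reticulum, rose by 0.31 (SE 0.0237), and HMGCS1, an enzyme of cholesterol synthesis, rose by 0.24 (SE 0.0292). The desaturase gene FADS2 rose by 0.20 (SE 0.023) and SREBF1, which encodes a SREBP, by 0.24 (SE 0.0388). Of 25 measured genes of cholesterol synthesis, 12 rose and 13 were not called, and 15 rose adjusted over the list alone (camera adjusted p = 3.9e-24, and adjusted p = 0.00732 with an estimated correlation); without day 3 replicate 2, 7 rose. Of 11 genes of fatty acid synthesis, 7 rose and 4 were not called, and 8 rose adjusted over the list alone (adjusted p = 5.46e-16, and adjusted p = 0.00482 with an estimated correlation).

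Single genes are ranked here among named genes with mean log2 CPM of 1 or more whose groups do not overlap, and genes with fewer reads or unnamed loci can lie beyond them. Within that limit at day 3 in MDA-MB-231, the cell adhesion gene NRCAM rose the most after G0S2 (log2 fold 1.21, SE 0.103), followed by MPPE1 (0.73, SE 0.128), CUBN (0.69, SE 0.12), C21orf91 (0.62, SE 0.0511) and ZFHX2 (0.58, SE 0.132). The steepest falls were in TNFSF15, a cytokine of the TNF family (-0.83, SE 0.0667), AQP5 (-0.71, SE 0.138), AKR1C2 (-0.61, SE 0.146), the non-coding RNA UCA1 (-0.61, SE 0.0466), CD34 (-0.60, SE 0.137) and ALPP (-0.58, SE 0.0458). The calls of NRCAM, MPPE1, C21orf91, TNFSF15, UCA1 and ALPP held in every setting tried. ZFHX2 was no longer called without control replicate 1 (adjusted p = 0.069), control replicate 2 (0.0604), day 3 replicate 1 (0.0607) or day 3 replicate 2 (0.146), and AQP5 without control replicate 1 (0.062). AKR1C2 was no longer called without control replicates 1, 2 or 3 (adjusted p = 0.126, 0.0604 and 0.0604) or day 3 replicates 2 or 3 (0.161 and 0.117). CD34 was no longer called without control replicates 1 or 3 (adjusted p = 0.097 and 0.0543) or day 3 replicates 1 or 3 (0.087 and 0.107).

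Several other lists moved by less in MDA-MB-231 at day 3. Of 22 NF-kB and cytokine genes, 5 fell and 17 were not called, and 6 fell adjusted over the list alone (camera adjusted p = 2.83e-05, and adjusted p = 0.033 with an estimated correlation). They included CSF1, the macrophage growth factor (-0.23, SE 0.0273), IER3 (-0.18, SE 0.0255) and NFKBIA (-0.23, SE 0.0373), which encodes an inhibitor of NF-kB. Without control replicate 3 or day 3 replicate 2, 3 of these genes fell, and the p with an estimated correlation rose to 0.0579, 0.07 and 0.0838 without control replicates 1, 2 and 3 and to 0.0766 and 0.068 without day 3 replicates 2 and 3. Of 19 TGF-beta targets, 3 fell, among them the matricellular gene CCN1 (-0.16, SE 0.0192), and 1 rose, as without control replicate 1 but in no other omission; 7 fell and 2 rose adjusted over the list alone (adjusted p = 0.000577, and adjusted p = 0.0493 with an estimated correlation). With an estimated correlation the TGF-beta call was lost without any single library (adjusted p = 0.0982, 0.0606 and 0.0846 without controls 1, 2 and 3, and 0.0724, 0.0801 and 0.0731 without day 3 replicates 1, 2 and 3).

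The hypoxia list had 4 rises and 1 fall among 19 genes at day 3 in MDA-MB-231, with 9 rises and 1 fall adjusted over the list alone (camera adjusted p = 3.04e-05, and adjusted p = 0.0281 with an estimated correlation). BNIP3 rose (0.19, SE 0.0288). The fall was lost in every omission. The number of rises was 2, 1, 2, 1 and 2 without control replicates 1 and 2 and day 3 replicates 1, 2 and 3, and with an estimated correlation the call was lost without controls 1, 2 or 3 (adjusted p = 0.0555, 0.0606 and 0.0569) or day 3 replicates 2 or 3 (0.0579 and 0.058). Growth lists were lower as lists with few called members: 1 of 36 DNA replication genes fell (6 adjusted over the list alone, adjusted p = 8.85e-07, and adjusted p = 0.0241 with an estimated correlation), 1 of 20 ribosome biogenesis genes (5 adjusted over the list alone, 6.88e-06 and 0.0241) and 2 of 32 mitosis genes (8 adjusted over the list alone, 3.34e-07, and adjusted p = 0.21 with an estimated correlation). The count of falls in mitosis went to 1 or none in every omission. In DNA replication no fall was left without control replicates 1 or 2 or any day 3 replicate, against 6 adjusted over the list alone and 12 at an unadjusted p under 0.05 in all libraries, while 2 fell without control replicate 3 (adjusted p = 0.0504 with an estimated correlation). In ribosome biogenesis no fall was left without control replicate 1 or day 3 replicates 1 or 2 (8 fell at an unadjusted p under 0.05 in all libraries), and 3 fell without control replicate 3; with an estimated correlation the call was lost without control replicate 3 (adjusted p = 0.0687) or day 3 replicate 2 (0.0558).

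A further 5 lists were called with the preset correlation at day 3 in MDA-MB-231 and lost with an estimated correlation. Of 14 heat shock genes 1 fell, HSPH1 (-0.14, SE 0.0234), and 7 fell adjusted over the list alone (adjusted p = 1.64e-05, and adjusted p = 0.0732 with an estimated correlation). Of 18 ER chaperone genes 2 rose and 5 rose adjusted over the list alone (0.000684, and adjusted p = 0.0972 with an estimated correlation); in single omissions at most 1 rose. The mitochondrial ribosome was lower (0.00895, and adjusted p = 0.234 with an estimated correlation), with none of 33 genes called by limma, 1 rise and 1 fall adjusted over the list alone, and 1 rise and 6 falls at an unadjusted p under 0.05; without control replicate 1 the adjusted p was 0.061, and without control replicate 3, 1 gene fell. ATF4 targets were higher (0.0426, and adjusted p = 0.389 with an estimated correlation), with none of 25 genes called by limma, 1 rise adjusted over the list alone and 4 at an unadjusted p under 0.05; the call was lost without control replicate 3 (0.259) or day 3 replicates 1 or 2 (0.153 and 0.0713). The type I interferon list was barely higher (0.0438, and adjusted p = 0.254 with an estimated correlation): of 47 genes 1 rose, SAMD9L (0.22, SE 0.0434), also adjusted over the list alone. SAMD9L was not called without control replicate 2 (adjusted p = 0.0604), and the interferon list was not called without control replicates 1 or 2 (0.115 and 0.112) or day 3 replicates 1 or 2 (0.0637 and 0.108).

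In all, 253 of 14308 genes were called at day 3 in MDA-MB-231, 128 higher and 125 lower, with a median absolute log2 fold of 0.17 among them; 4 rose and none fell by over 2-fold. Besides G0S2 and NRCAM these 4 were GCG, named after its values were seen and with hardly any control reads, and an unnamed locus. The groups did not overlap in 2928 genes (20.5%; chance gives 10%). The count fell to 138 and 121 without control replicates 1 and 2, and to 121, 119 and 147 without day 3 replicates 1, 2 and 3. Of 39 named calls other than G0S2, 23 held with each library left out.

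By day 15 in MDA-MB-231, inflammatory and epithelial genes were lower and the rise of the lipid synthesis lists was no longer called. CCL2, a chemokine that attracts monocytes, fell by a log2 fold of 0.70 (SE 0.101), the chemokine CXCL8 fell by 0.47 (SE 0.0942), and ICAM1, an adhesion molecule for leukocytes, fell by 0.42 (SE 0.0395). Of 22 NF-kB and cytokine genes, 10 fell and 12 were not called. Adjusted over the list alone, 11 fell (camera adjusted p = 2.13e-10 and 0.0124). Among epithelial genes, CDH1, which encodes E-cadherin, fell by 0.81 (SE 0.186, from a mean of 71.3 control reads), ELF3, an epithelial transcription factor, by 0.71 (SE 0.117) and the tight junction gene CLDN7 by 0.38 (SE 0.0818). Of 20 epithelial genes 10 fell and 10 were not called, and 13 fell adjusted over the list alone (3.97e-09 and 0.0892); without control replicate 1, 6 fell.

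Some matrix and migration genes also fell at day 15 in MDA-MB-231. Of 36 migration and matrix proteolysis genes, 15 fell, 1 rose and 20 were not called, with 19 falls and 4 rises adjusted over the list alone (camera adjusted p = 3.04e-05, and adjusted p = 0.0974 with an estimated correlation); 7 and 8 fell without control replicates 1 and 2, and 3, 2 and 4 rose without control replicate 3 and day 15 replicates 1 and 2. The integrin gene ITGB3 fell by 0.43 (SE 0.0767). Of 19 TGF-beta targets 7 fell and 12 were not called, with 9 falls adjusted over the list alone (8.4e-05 and 0.033), among them ID2 (-0.42, SE 0.0937) and CCN1 (-0.17, SE 0.0192). Without control replicate 2, 3 of them fell, and with an estimated correlation the TGF-beta call was lost without controls 1 or 3 (adjusted p = 0.058 and 0.0772) or day 15 replicates 1, 2 or 3 (0.0556, 0.065 and 0.055). The mesenchymal list was not called (0.175), with 6 falls, among them THBS1 (-0.21, SE 0.017), 3 rises and 17 genes not called, and with 6 falls and 5 rises adjusted over the list alone; 1 fell without control replicate 2 and 3 without day 15 replicate 1, and 1 rose without control replicate 1.

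Other lists at day 15 in MDA-MB-231 were called with the preset correlation and lost with an estimated correlation. Mitosis genes were higher, with 6 of 32 called, among them TTK, a spindle checkpoint kinase (0.16, SE 0.032), and 11 rises and 1 fall adjusted over the list alone (camera adjusted p = 1.64e-05, and adjusted p = 0.267 with an estimated correlation); 3, 2 and 12 rose without control replicates 1, 2 and 3, and 15 and 3 without day 15 replicates 2 and 3. Cytosolic ribosomal proteins were higher, with 7 of 47 called, among them RPS25 (0.13, SE 0.0243), and 12 rises adjusted over the list alone (0.00367 and 0.421). Their rises numbered 2 and 1 without control replicates 1 and 2, 3 without day 15 replicates 1 or 3 and 11 (with 4 falls) without day 15 replicate 2, and the list was not called without control replicate 3 (0.262) or day 15 replicate 2 (0.185). Antigen presentation was lower, with 3 falls, 1 rise and 18 of 22 genes not called, and 9 falls and 1 rise adjusted over the list alone (0.000684 and 0.115); 8 fell without control replicate 3 or day 15 replicate 2, and the rise was lost without control replicates 1 or 2 or day 15 replicates 1 or 2. Luminal markers were lower, with 2 of 11 called, KRT8 (-0.22, SE 0.0261) and KRT18 (-0.17, SE 0.0269), and 3 falls adjusted over the list alone (0.0292 and 0.192); the list was not called without control replicate 1 (0.0673) or day 15 replicate 1 (0.0584). Replication-dependent histones, a list that tracks RNA quality, were lower alongside these lists (list median -0.17, adjusted p = 0.0345, and adjusted p = 0.389 with an estimated correlation), with none of 8 called by limma and 3 falls at an unadjusted p under 0.05; the call was lost without control replicate 2 (0.0775) or day 15 replicates 1 or 3 (0.101 and 0.115), and 2 fell without day 15 replicate 2.

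Within the same limit on reads and overlap, the largest rises at day 15 in MDA-MB-231 after G0S2 were in NRCAM (1.34, SE 0.103), CUBN (0.60, SE 0.12), LPL, which encodes lipoprotein lipase (0.59, SE 0.139), ZNF641 (0.57, SE 0.0653) and C21orf91 (0.54, SE 0.0511). The steepest falls within it were in CST1 (-1.17, SE 0.0672), TNFSF15 (-1.13, SE 0.0667), LGALS12 (-0.88, SE 0.129), MAGEC1 (-0.82, SE 0.12), ALPP (-0.78, SE 0.0458) and AQP5 (-0.77, SE 0.138). GDF15, a stress-induced cytokine, fell by 0.69 (SE 0.125), while the ATF4 target list it belongs to was not called (adjusted p = 0.158) and the cystine transporter gene SLC7A11 rose by 0.20 (SE 0.031). In the interferon list 3 genes rose, 4 fell and 40 of 47 were not called (0.84); TRIM22 fell by 0.65 (SE 0.128) and BST2 by 0.24 (SE 0.0362). The falls numbered 2 and 6 without control replicates 1 and 3. In that list the median (-0.01) and the test pointed down and the mean (0.002) up, with 5 rises and 8 falls adjusted over the list alone.

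At day 15, 1173 of 14308 genes were called in MDA-MB-231, 490 higher and 683 lower, with a median absolute log2 fold of 0.16; 4 rose and 6 fell by over 2-fold, most of them with few reads, and the groups did not overlap in 3470 genes (24.3%; chance gives 10%). The count was 471, 457 and 1768 without control replicates 1, 2 and 3, and 698, 1897 and 721 without day 15 replicates 1, 2 and 3. Of 73 named calls other than G0S2, 45 held with each library left out.

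Between day 3 and day 15 in MDA-MB-231, the lipid synthesis lists fell and mitosis genes rose. Genes named for this comparison were chosen after their values were seen. SREBF1 fell by 0.40 (SE 0.0388), SCD by 0.35 (SE 0.0178) and INSIG1 by 0.23 (SE 0.0237) from day 3 to day 15. Of 25 genes of cholesterol synthesis 13 fell and 12 were not called. Adjusted over the list alone, 19 fell (camera adjusted p = 3.78e-16 and 0.0146). Without day 3 replicate 1, 7 of them fell, and without day 15 replicate 2 the adjusted p with an estimated correlation was 0.0546. Of 11 genes of fatty acid synthesis 8 fell, as adjusted over the list alone (7.07e-12 and 0.00875). Of 32 mitosis genes 18 rose and 28 rose adjusted over the list alone (6.23e-20 and 0.0458), among them TTK (0.19, SE 0.032) and BUB1, a spindle checkpoint kinase (0.14, SE 0.0228). The mitosis rises numbered 5 without day 3 replicates 1 or 2, and 7 and 8 without day 15 replicates 1 and 3. With an estimated correlation the mitosis call was lost without day 3 replicates 1, 2 or 3 (adjusted p = 0.0763, 0.0774 and 0.0646) or day 15 replicates 1 or 2 (0.0749 and 0.0679). Of 36 DNA replication genes 8 rose, and 14 adjusted over the list alone (1.46e-06 and 0.0225). Of 20 ribosome biogenesis genes 5 rose, and 7 adjusted over the list alone (1.82e-07 and 0.0146). Without day 3 replicates 1, 2 and 3 and day 15 replicates 1 and 3, 1, 1, 5, 3 and 4 DNA replication genes rose and 0, 0, 4, 1 and 3 ribosome biogenesis genes (limma; 11 of the latter at an unadjusted p under 0.05 with all libraries). Without day 15 replicate 2 both calls were lost with an estimated correlation (adjusted p = 0.0783 and 0.057). Of 19 hypoxia genes 5 fell, as adjusted over the list alone (0.000485), and of 22 NF-kB and cytokine genes 4 fell, with 6 adjusted over the list alone (0.000193), each with adjusted p = 0.0458 with an estimated correlation. With an estimated correlation the hypoxia call was lost without day 3 replicates 1, 2 or 3 (0.0604, 0.0569 and 0.075) or day 15 replicates 1, 2 or 3 (0.0599, 0.0909 and 0.0567), and the NF-kB call without day 3 replicates 1, 2 or 3 (0.063, 0.0569 and 0.0604) or day 15 replicates 1 or 2 (0.0847 and 0.127). Without day 3 replicates 1 and 2 and day 15 replicate 1, the falls numbered 1, 1 and 2 in hypoxia and 1, 2 and 2 in NF-kB genes, and in hypoxia 2 without day 3 replicate 3 and 1 without day 15 replicate 3. MDA-MB-231 identity genes were higher beside these lists, with 3 of 12 called and 4 adjusted over the list alone (0.0277 and 0.136; 0.0521 without day 3 replicate 3), and 1 rose without day 3 replicates 1 or 2. In all, 763 genes were called, 354 higher and 409 lower at day 15, and the groups did not overlap in 3585 genes (25.1%; chance gives 10%). The count was 124 and 143 without day 3 replicates 1 and 2, and 308, 1664 and 319 without day 15 replicates 1, 2 and 3.

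In T47D, the comparison of day 3 with control asks the same of receptor-positive cells, and interferon-stimulated genes rose together by large amounts. IFI27 rose by a log2 fold of 5.58 (SE 0.198), OAS1 by 5.50 (SE 0.167), IFI44 by 5.09 (SE 0.237), OAS2 by 4.70 (SE 0.082) and IFIT1 by 4.66 (SE 0.0611). XAF1 rose by 4.81 (SE 0.256). Of 47 measured genes of the type I interferon list, 46 rose and 1 was not called, also adjusted over the list alone, with a list median of 2.50 (camera adjusted p = 5.36e-206, and adjusted p = 2.98e-06 with an estimated correlation). ISG20 was the gene not called (-0.17, adjusted p = 0.883), named after its value was seen. Control levels of several of these genes were low, with a mean of 16.7 reads for IFI27, 21 for OAS1, 7.3 for IFI44 and 5 for XAF1, so their folds depend on the pseudocount.

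Genes of antigen presentation and a few cytokine genes rose with them in T47D at day 3. NLRC5, a regulator of MHC class I genes, rose by 1.24 (SE 0.164), the immunoproteasome genes PSMB9 and PSMB8 by 1.14 (SE 0.139) and 0.67 (SE 0.0586), and HLA-F by 0.93 (SE 0.0972). Of 18 antigen presentation genes, 13 rose and 5 were not called. Adjusted over the list alone, 16 rose (camera adjusted p = 3.55e-31 and 0.0128). Of 15 NF-kB and cytokine genes 2 rose, and 3 rose adjusted over the list alone (1.03e-05 and 0.0242). They were the chemokine gene CCL5 (3.39, SE 0.161) and TNFAIP3, which encodes an inhibitor of NF-kB (0.72, SE 0.136). Without control replicate 2 or day 3 replicate 2 only CCL5 rose, with an adjusted p of 0.0524 and 0.0785 for TNFAIP3, and without day 15 replicate 2, 4 rose. Replication-dependent histones, the list fixed as a check on RNA quality, were higher beside these groups, with 2 of 7 called, and 3 adjusted over the list alone (0.0152 and 0.115). Of these H1-2 rose by 0.27 (SE 0.0385), and 1 histone gene rose when any one control or day 3 library was left out.

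**Figure D2:**
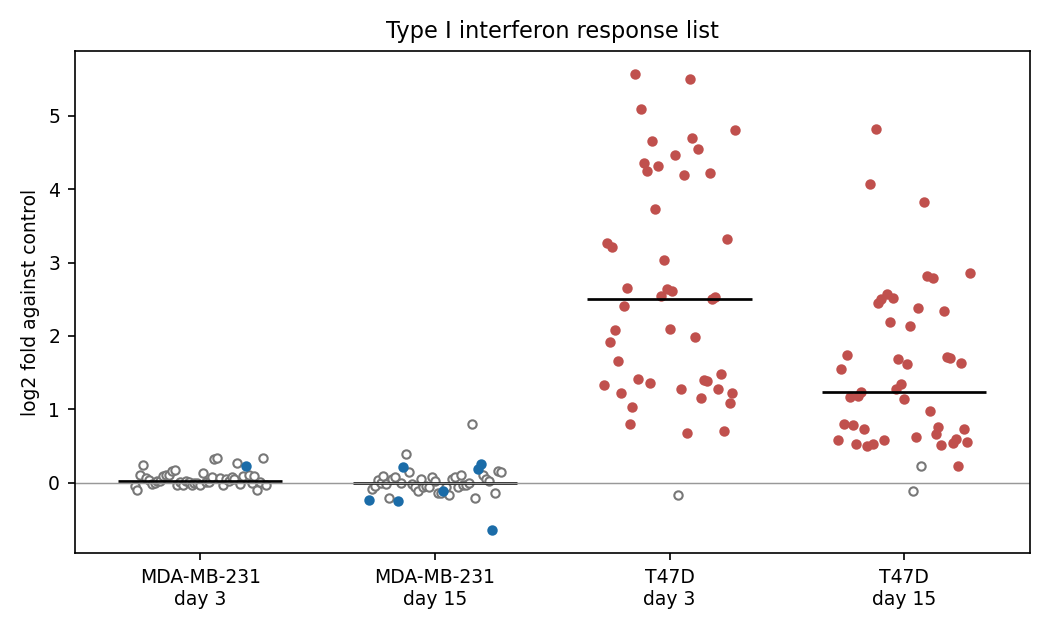
Log2 fold against control of each measured gene of the type I interferon list in the 4 comparisons; filled points are called genes, open points genes not called, and lines the list median. In T47D 46 and 45 of 47 genes rose at days 3 and 15, with medians of 2.50 and 1.24, against 1 and 3 of 47 in MDA-MB-231.

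Falls in T47D at day 3 were smaller than these rises. The calcitonin receptor gene CALCR fell by 0.36 (SE 0.0439). This held in every setting tried, as did falls of PDZK1 (-0.22, SE 0.0372), THBS1 (-0.20, SE 0.0286) and CAPN2 (-0.27, SE 0.0313). The larger falls given next depended on single libraries. CXCR4, a chemokine receptor gene (-0.73, SE 0.142), was not called without control replicates 1 or 2 (adjusted p = 0.0695 and 0.0804) or day 3 replicates 1 or 3 (0.0916 and 0.0701). PPP1R1A (-0.69, SE 0.146) was not called without controls 1, 2 or 3 (adjusted p = 0.114, 0.11 and 0.1) or day 3 replicates 2 or 3 (0.0589 and 0.121). TFF3, an estrogen-induced trefoil factor (-0.63, SE 0.138), and SHISA2 (-0.56, SE 0.129) were not called when any one library of the compared groups was left out. The adjusted p without controls 1, 2 and 3 and day 3 replicates 1, 2 and 3 was 0.136, 0.0877, 0.153, 0.126, 0.134 and 0.144 for TFF3, and 0.208, 0.101, 0.146, 0.12, 0.217 and 0.0523 for SHISA2.

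The estrogen-induced list was lower at day 3 in T47D with few called members. Of 45 genes 5 fell, 1 rose and 39 were not called, with 10 falls and 3 rises adjusted over the list alone (camera adjusted p = 0.00518, and adjusted p = 0.0978 with an estimated correlation). The falls numbered 3 when any one library of the compared groups was left out and 11 without day 15 replicate 2, where 3 rose; none rose without control replicates 1 or 3 or day 3 replicate 2 (3 at an unadjusted p under 0.05 in all libraries). ATF4 targets, which serve amino acid supply and stress, were lower, with 2 of 25 called and 5 falls adjusted over the list alone (3.34e-07 and 0.07). Their falls numbered none without day 3 replicate 1 (13 at an unadjusted p under 0.05 in all libraries), 1 without each other library of the compared groups and 11 without day 15 replicate 2. SLC7A11, an ATF4 target, fell by 0.27 (SE 0.0469) and was not called without day 3 replicate 1 (adjusted p = 0.051). T47D identity genes were lower (0.0173 and 0.115), with 3 of 12 called and 3 falls and 1 rise adjusted over the list alone. The 3 are TFF3, PGR and AGR2, which the luminal list also holds, and luminal markers were not called as a list (0.164), with the same 3 falls among 19 genes and 4 falls and 1 rise adjusted over the list alone. In both lists at most 1 fell with any library of the compared groups left out, and without day 15 replicate 2, 5 luminal markers fell and 2 rose, and 1 identity gene rose.

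Of the other lists in T47D at day 3, 7 were lower with the preset correlation and lost with an estimated correlation. Of 14 mesenchymal genes 1 fell, with 3 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.0233, and adjusted p = 0.12 with an estimated correlation; 0.0841 without control replicate 3). Of 23 fatty acid oxidation genes 1 fell, also adjusted over the list alone (0.0178 and 0.109; 0.0519 without control replicate 3). Of 18 p53 targets 1 fell, also adjusted over the list alone (0.0406 and 0.147). The p53 call was lost without control replicate 1 (0.083) or day 3 replicate 3 (0.0598), and the p53 fall without control replicate 3 or day 3 replicates 1 or 2. Basal markers (0.0292 and 0.142), cholesterol synthesis (0.0441 and 0.234), hypoxia (0.047 and 0.234) and lysosome genes (0.00895 and 0.44) had no member called by limma, with 4, 3, 3 and 4 falls at an unadjusted p under 0.05 among 9, 24, 17 and 22 genes. Only the lysosome list had a fall, 1, adjusted over the list alone. Basal markers were not called without control replicate 2 (0.0721) or day 3 replicate 1 (0.0595), and lysosome genes without control replicate 3 (0.0841). Cholesterol synthesis was not called without control replicates 1 or 3 (0.0604 and 0.0906) or day 3 replicates 2 or 3 (0.0816 and 0.112). Hypoxia was not called without control replicates 1 or 3 (0.119 and 0.0688), day 3 replicates 1 or 2 (0.066 and 0.0959) or day 15 replicate 2 (0.0789). Without day 15 replicate 2, 2 mesenchymal, 3 fatty acid oxidation, 2 p53, 1 basal, 3 cholesterol synthesis, 1 hypoxia and 4 lysosome genes fell, and 1 mesenchymal and 1 cholesterol synthesis gene rose.

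In all, 277 of 14768 genes were called at day 3 in T47D, 171 higher and 106 lower, with a median absolute log2 fold of 0.47; 79 rose and none fell by over 2-fold. The groups did not overlap in 3234 genes (21.9%; chance gives 10%). The count was 182 without day 3 replicate 1. It was 746 (333 higher, 413 lower) without day 15 replicate 2, a library outside this comparison whose spread enters the fit. Of 31 named calls other than G0S2, 18 held with each library left out.

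At day 15 in T47D the interferon genes were still higher, by less, and many other genes had moved. IFI44 rose by 4.82 (SE 0.237), IFI27 by 4.07 (SE 0.198), OAS1 by 3.82 (SE 0.167), XAF1 by 2.85 (SE 0.256) and OAS2 by 2.82 (SE 0.082) against control. Of 47 interferon genes 45 rose and 2 were not called, also adjusted over the list alone, with a list median of 1.24 (camera adjusted p = 5.95e-74, and adjusted p = 3.39e-05 with an estimated correlation). The 2 were ISG20 (-0.12, adjusted p = 0.783) and MX2 (0.23, adjusted p = 0.335), named after their values were seen. Of 18 antigen presentation genes 13 rose and 5 were not called, with 14 rises adjusted over the list alone (4.65e-12 and 0.056). HLA-F rose by 0.80 (SE 0.0972), and 8 genes of the list rose without control replicate 2. TES, which encodes a focal adhesion protein and is in none of the lists, rose by 4.73 (SE 0.0879) from a control mean of 30.7 reads.

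Of the lists lower at day 15 in T47D, only ATF4 targets and fatty acid oxidation held with an estimated correlation. SLC7A5, an amino acid transporter gene, fell by 0.64 (SE 0.0742), PSAT1, an enzyme of serine synthesis, by 0.53 (SE 0.111), and the stress genes NUPR1 and DDIT3 by 0.48 (SE 0.0541) and 0.47 (SE 0.0629). Of 25 ATF4 targets 16 fell and 9 were not called. Adjusted over the list alone, 20 fell (camera adjusted p = 1.69e-13 and 0.0241). Of 23 fatty acid oxidation genes 11 fell, 1 rose and 11 were not called, with 13 falls and 1 rise adjusted over the list alone (1.03e-05 and 0.0241). PPARGC1A, a regulator of mitochondrial genes, fell by 0.53 (SE 0.0594) and PPARA, a regulator of fatty acid oxidation, by 0.41 (SE 0.0638). The rise was in PPARG, known for its part in fat storage (0.60, SE 0.16). PPARG was not called without control replicates 1 or 3 (adjusted p = 0.0783 and 0.0908) or day 15 replicates 1 or 3 (0.0795 and 0.0632), and 7 genes of the list fell without day 15 replicate 1. Of 42 nuclear respiratory chain genes 9 fell and 1 rose, with 12 falls and 1 rise adjusted over the list alone (1.4e-05 and 0.0978), among them SDHA (-0.19, SE 0.0325). Their falls numbered 5 and 4 without control replicates 1 and 2, and 3 and 22 without day 15 replicates 1 and 2; the rise was lost without control replicates 2 or 3, and 3 rose without day 15 replicate 2. Of 22 lysosome genes 8 fell, with 10 falls adjusted over the list alone (9.04e-06 and 0.239), among them TPP1 (-0.22, SE 0.0347), and 18 fell without day 15 replicate 2. Of 19 glycolysis genes 3 fell, with 5 falls adjusted over the list alone (0.0229 and 0.446), among them GPI (-0.28, SE 0.0397). The glycolysis call was lost without control replicate 3 (0.103) or day 15 replicate 3 (0.0985), and 8 fell without day 15 replicate 2.

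**Figure D3:**
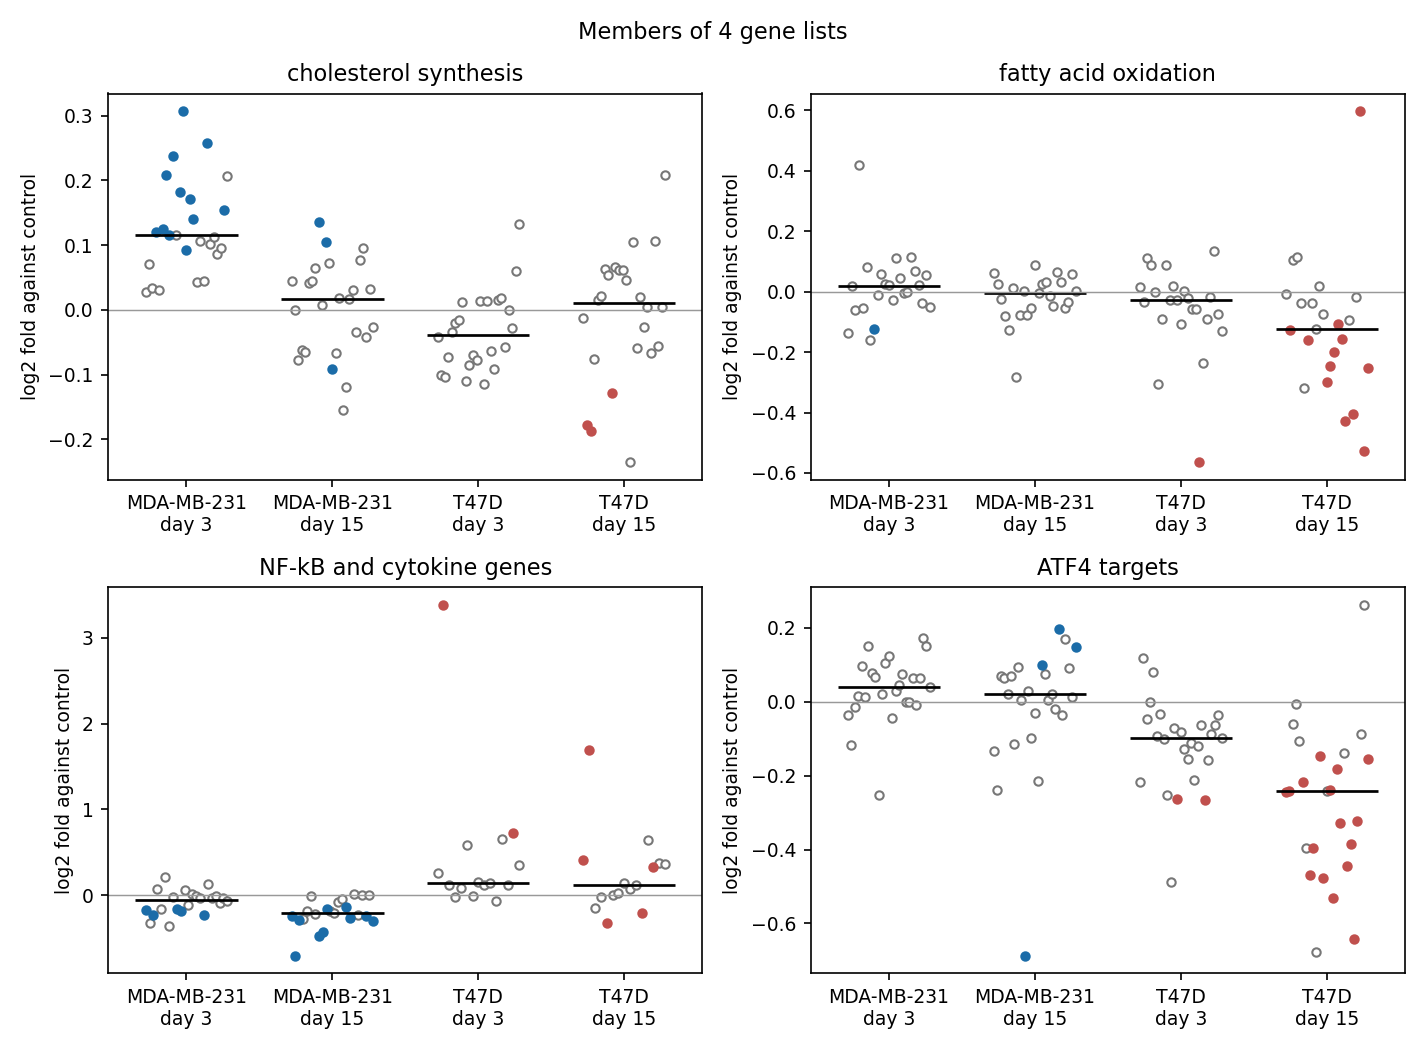
Log2 fold against control of each measured gene of 4 lists in the 4 comparisons; filled points are called genes, open points genes not called, and lines the list median. Cholesterol synthesis rose in MDA-MB-231 at day 3 (12 of 25 genes), NF-kB and cytokine genes fell there at day 15 (10 of 22), and ATF4 targets (16 of 25) and fatty acid oxidation (11 of 23) fell in T47D at day 15.

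Estrogen-related genes moved both ways at day 15 in T47D. TFF1, a classical estrogen-induced gene, fell by 1.21 (SE 0.134), KRT13 by 1.34 (SE 0.145), CALCR by 1.40 (SE 0.0439) and PGR, the progesterone receptor gene, by 0.18 (SE 0.0293), while the early growth response gene EGR3 rose by 1.13 (SE 0.204). Of 45 estrogen-induced genes 11 rose, 10 fell and 24 were not called, with 13 rises and 11 falls adjusted over the list alone, and the list was not called (camera adjusted p = 0.501). The rises numbered 7 without control replicates 1 or 2. Of 19 luminal markers 8 fell, 2 rose and 9 were not called, with 9 falls and 4 rises adjusted over the list alone (0.0233, and adjusted p = 0.115 with an estimated correlation). TFF3 fell by 0.92 (SE 0.138), AGR2 by 0.27 (SE 0.0261) and ESR1, the estrogen receptor gene, by 0.16 (SE 0.0293). Without control replicate 3 the luminal list was not called (0.0505), and without day 15 replicate 2, 4 rose. T47D identity genes were not called as a list (0.305), with 4 falls and 3 rises among 12 genes, and 5 falls and 4 rises adjusted over the list alone; 1 rose without control replicates 1 or 2 or day 15 replicate 1.

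Among matrix, mesenchymal and migration genes at day 15 in T47D, several fell and others rose or were not called. TNC, which encodes tenascin C, fell by 2.82 (SE 0.274) from a control mean of 53.3 reads to 5 reads, the collagen gene COL3A1 by 1.08 (SE 0.0746), CD44 by 0.54 (SE 0.0922) and THBS1 by 0.49 (SE 0.0286). Of 14 mesenchymal genes 6 fell, 1 rose and 7 were not called, as adjusted over the list alone (camera adjusted p = 0.0133, and adjusted p = 0.109 with an estimated correlation). The migration and matrix proteolysis list was not called (0.414), with 6 falls, 5 rises and 19 of 30 genes not called, as adjusted over the list alone for the called genes. The rises numbered 3, 2, 3 and 2 without control replicates 1, 2 and 3 and day 15 replicate 1. Among its genes MET, a growth factor receptor gene, fell by 1.40 (SE 0.237), CXCR4 by 0.73 (SE 0.142) and CAPN2 by 0.50 (SE 0.0313). Some lists of other cells were lower at the same time. MDA-MB-231 identity genes were lower, with 3 of 4 called, also adjusted over the list alone (0.0152 and 0.115; 0.0629 without day 15 replicate 3). Fibroblast markers were lower, with 1 of 2 called, COL3A1, also adjusted over the list alone (0.0292 and 0.234). The fibroblast call was lost without control replicate 3 (0.0758) or day 15 replicate 3 (0.0593).

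Mitosis genes were higher at day 15 in T47D, with 6 of 32 called and 10 rises adjusted over the list alone (camera adjusted p = 1.29e-05, and adjusted p = 0.271 with an estimated correlation), among them the mitotic kinase gene PLK1 (0.21, SE 0.0335). Their rises numbered 1, 1 and 3 without control replicates 1, 2 and 3, and 2 and 23 without day 15 replicates 1 and 2. Replication-dependent histones were not called as a list (0.082), with 3 of 7 genes higher, also adjusted over the list alone. Other falls of genes taken by the naming rule were in SLC6A14, an amino acid transporter gene (-2.78, SE 0.0604), PMP2 (-1.69, SE 0.194), KITLG, the ligand of KIT (-1.48, SE 0.0526), INHBA (-1.40, SE 0.097), and SHISA2 (-1.37, SE 0.129). Among lipid droplet and lipolysis genes 2 rose and 2 fell of 16 (0.838), with 2 rises and 3 falls adjusted over the list alone; 1 rose without control replicates 1 or 2, and 1 and 4 fell without control replicate 1 and day 15 replicate 2. DGAT2, an enzyme of triglyceride synthesis, rose by 0.72 (SE 0.123) and the fatty acid transporter gene CD36 fell by 0.45 (SE 0.0919).

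At day 15, 1659 of 14768 genes were called in T47D, 739 higher and 920 lower, with a median absolute log2 fold of 0.27; 67 rose and 44 fell by over 2-fold. The groups did not overlap in 3888 genes (26.3%; chance gives 10%). The count was 1006 and 930 without control replicates 1 and 2, and 999 and 3705 without day 15 replicates 1 and 2. Day 15 replicate 2 stood apart from the other 2 libraries of its group: the chi-square per degree of freedom of its pairs was 14.52 and 23.59, against 1.736 to 5.919 for the other pairs of libraries within groups. Of 93 named calls other than G0S2, 61 held with each library left out.

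From day 3 to day 15 in T47D the interferon list declined. Of 47 genes 43 fell and 4 were not called. The list median was -0.98, with 44 falls adjusted over the list alone (camera adjusted p = 2.17e-84 and 2.28e-05). Genes named for this comparison were chosen after their values were seen. ISG15 fell by 2.34 (SE 0.225) and IFIT1 by 2.09 (SE 0.0611), while IFI44 was not called (-0.27, adjusted p = 0.638). The respiratory chain, fatty acid oxidation and ATF4 lists also fell, with 7 of 42, 5 of 23 and 6 of 25 genes called. Adjusted over the list alone, 16, 6 and 9 genes of these lists fell, and 1 fatty acid oxidation gene rose. The camera adjusted p was 7.24e-10, 0.00117 and 1.12e-07, and adjusted p = 0.0446, 0.0458 and 0.0494 with an estimated correlation. With an estimated correlation these 3 calls were lost in most omissions: without day 3 replicates 1 and 2 and day 15 replicates 1 and 3, the adjusted p was 0.0571, 0.0638, 0.0684 and 0.0693 for the respiratory chain, 0.0717, 0.0659, 0.0921 and 0.111 for fatty acid oxidation and 0.0717, 0.0659, 0.0922 and 0.111 for ATF4 targets. Without day 3 replicate 3 it was 0.0709 for both of the last lists, and without day 15 replicate 2 it was 0.0675 for ATF4 targets. Without day 15 replicate 2, 24 respiratory chain genes, 10 fatty acid oxidation genes and 15 ATF4 targets fell. Without day 3 replicates 1, 2 and 3 and day 15 replicate 1, the falls numbered 2, 3, 3 and 4 in the respiratory chain, 3, 3, 3 and 4 in fatty acid oxidation and 3, 4, 5 and 4 in ATF4 targets. Lists of other cells were lower beside them, with 1 of 2 fibroblast markers called (0.0122 and 0.147) and 1 of 4 MDA-MB-231 identity genes (0.0292 and 0.138), and 1 and 2 genes adjusted over the list alone. The identity call was lost without day 3 replicate 3 (0.0626) or day 15 replicate 3 (0.131), and 0 (limma; 2 at an unadjusted p under 0.05 in all libraries) and 2 of its genes fell without day 3 replicate 1 and day 15 replicate 2. In all, 824 genes were called, 330 higher and 494 lower, and the groups did not overlap in 3302 genes (22.4%; chance gives 10%). The count was 409, 403 and 457 without day 3 replicates 1, 2 and 3, and 478 and 2604 without day 15 replicates 1 and 2.

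The panel fixed in advance covers hormone receptors, growth regulators and lipolysis genes. In MDA-MB-231, ESR1, PGR, TFF1 and FOXA1 were not listed and were not analysed here. VIM rose at day 15 by 0.11 (SE 0.0171, adjusted p = 6.98e-05) and was not called at day 3 (0.04, adjusted p = 0.323). PNPLA2 fell at day 15 by 0.24 (SE 0.0435) and was not called at day 3 (-0.08, adjusted p = 0.457). CDH1 fell at day 15 as given above and was not called at day 3 (-0.67, SE 0.186, adjusted p = 0.0642). GREB1 rose at day 15 by 0.47 (SE 0.137, adjusted p = 0.0327) and was not called at day 3 (0.48, adjusted p = 0.0763). Its day 15 call was lost without control replicates 1, 2 or 3 (adjusted p = 0.091, 0.0866 and 0.0602) or day 15 replicates 1, 2 or 3 (0.0823, 0.0601 and 0.063). GATA3, MYC, CCND1 and PLIN2 were not called at day 3 (-0.12, 0.004, -0.02 and -0.04) or day 15 (-0.13, -0.008, -0.01 and -0.04).

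In T47D, VIM was not listed and was not analysed here. At day 15 ESR1, PGR and TFF1 fell as given above, and GATA3, a luminal transcription factor, rose by 0.18 (SE 0.0288, adjusted p = 0.000869), a call lost with the GC correction (adjusted p = 0.0846). CCND1 rose by 0.11 (SE 0.0291, adjusted p = 0.0211) and CDH1 by 0.10 (SE 0.0244, adjusted p = 0.0215). CCND1 was not called without controls 1, 2 or 3 (adjusted p = 0.0611, 0.0729 and 0.0803), nor CDH1 without controls 1, 2 or 3 (0.0711, 0.0951 and 0.0613) or day 15 replicate 1 (0.0751). GREB1, FOXA1, MYC, PNPLA2 and PLIN2 were not called at day 15 (-0.02, -0.01, -0.02, 0.08 and -0.01). At day 3 PGR fell by 0.13 (SE 0.0293, adjusted p = 0.035), a call lost without controls 1, 2 or 3 (adjusted p = 0.206, 0.18 and 0.0577) or day 3 replicates 1, 2 or 3 (0.201, 0.0847 and 0.208). TFF1 (-0.52, SE 0.134, adjusted p = 0.073) and GATA3 (0.11, adjusted p = 0.0788) were not called at day 3, nor were ESR1, GREB1, FOXA1, MYC, CCND1, CDH1, PNPLA2 and PLIN2 (-0.01, 0.04, -0.01, 0.01, 0.04, -0.007, -0.01 and 0.05).

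Markers of other cells that are not given above were not called as lists. At days 3 and 15 in MDA-MB-231, the camera adjusted p was 0.723 and 0.261 for fibroblast markers (4 genes), 0.85 and 0.873 for leukocyte markers (5 genes) and 0.173 and 0.391 for endothelial markers (2 genes). It was 0.723 and 0.127 for MDA-MB-231 identity genes (12 genes), 0.748 and 0.266 for T47D identity genes (7 genes) and 0.255 for histones at day 3 (8 genes). Called members of these lists in MDA-MB-231 were 1 fibroblast marker and 1 T47D identity gene, which fell, and 2 MDA-MB-231 identity genes, which rose, each at day 15. Without control replicate 1 only 1 of these 2 rose, and without control replicate 3 or day 15 replicate 2 1 of that list fell. In T47D it was 0.339 for fibroblast markers at day 3, 0.838 and 0.501 for leukocyte markers (2 genes) at days 3 and 15 and 0.177 for MDA-MB-231 identity genes at day 3 (4 genes). In a few lists that were not called, the median, mean and test differed in sign. At day 15 in MDA-MB-231 the hypoxia and ATF4 lists had medians of 0.006 and 0.02, means of -0.05 and -0.02 and an upward test. The glycolysis and lipid droplet lists had medians of -0.02 and -0.04, means of 0.001 and 0.02 and a downward test, and the mitochondrial ribosome a median of 0.006, a mean of -0.001 and an upward test. At day 3 in MDA-MB-231 the lipid droplet and leukocyte lists had medians of 0.003 and 0.02, means of -0.03 and -0.05 and a downward test. There the T47D identity list had a median of 0.06, a mean of -0.04 and an upward test, and the respiratory chain a median and mean of 0.001 and a downward test. In T47D the TGF-beta list at day 3 (median 0.03, mean -0.007) and the epithelial list at day 15 (0.002 and -0.008) had a downward test, and cholesterol synthesis at day 15 (0.01 and -0.008) an upward test.

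Day 3 and day 15 calls overlapped within each line. In MDA-MB-231, 55 genes were higher and 82 lower at both times, 4 were called in opposite directions, and independent calls would give 4.38 and 5.97. In T47D, 131 were higher and 89 lower at both times and 2 were opposite, against 8.56 and 6.6. Both comparisons use the same 3 controls, too few to split. In 50 simulations with shared controls and no change, at most 1 gene was called at both times. With no change few calls arise, so this decides nothing about the overlap. The folds at the 2 times correlated across genes with r = 0.563 in MDA-MB-231 and 0.692 in T47D, against 0.498 and 0.50 from shared controls alone, and genes are not independent replicates. In MDA-MB-231 the shared rises numbered 22 and 25 without control replicates 1 and 2, 24, 27 and 32 without day 3 replicates 1, 2 and 3 and 35 without day 15 replicate 1. The shared falls numbered 51, 49 and 54 without control replicates 1 and 2 and day 3 replicate 2. In T47D the shared rises and falls numbered 231 and 284 without day 15 replicate 2. The falls numbered 40, 34 and 50 without control replicates 1 to 3, and 35, 42 and 41 without day 3 replicates 1 to 3.

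Side by side, few genes were called in both lines at day 3 and more at day 15. Of the 12666 genes in both tables, 10 were called in both lines at day 3, 8 higher and 2 lower in both, where independent calls would give 1.5 and 0.57. At day 15, 167 were called in both lines, 27 higher and 69 lower in both and 71 in opposite directions, where independent calls would give 20.9 and 37.7 in the same direction. Fatty acid and cholesterol synthesis rose in MDA-MB-231 at day 3 (7 of 11 and 12 of 25 genes) and had no call in T47D at day 3 by limma among 12 and 24 genes. At an unadjusted p under 0.05, 1 fatty acid synthesis gene rose and 1 fell there, and 3 cholesterol synthesis genes fell. Without day 15 replicate 2, 1 fatty acid synthesis and 3 cholesterol synthesis genes were called lower there and 1 cholesterol synthesis gene higher. The interferon list had medians of 2.50 and 1.24 in T47D and of 0.02 and -0.01 in MDA-MB-231 at days 3 and 15. Its mean log2 CPM in control libraries was higher in MDA-MB-231 (3.87 to 3.92) than in T47D (2.01 to 2.07). Estrogen-induced genes were not called as a list in MDA-MB-231 at day 3 (camera adjusted p = 0.177; 2 of 33 fell, with 3 rises and 3 falls adjusted over the list alone) or day 15 (0.215; 3 rose and 3 fell, with 3 and 4 adjusted over the list alone). At day 15 the rises there numbered 1 without control replicates 1 or 2 or day 15 replicate 1. A test of these differences, chosen after the data were seen, is in the closing section.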

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

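The fit over both lines was chosen after the data were seen, as were the tests by quantile normalization and on the other line at the same dose; the test on MDA-MB-231 marker genes was written down before. That fit covers the 18 libraries and the 12666 genes of both tables, and tests for each gene whether the change against control differed between the lines. A constant scaling difference between the tables drops out of such a comparison. All that follows in this part stands here because the response differed between T47D and MDA-MB-231.

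The day 3 response differed in 311 genes (178 more positive and 133 more negative in T47D), and the day 15 response in 1196 genes (516 and 680). Of 100 splits of the libraries within each line, 1, the real one, gave as many genes at day 3 and at day 15. The highest of the others gave 190 and 944. The splits assume no response in either line and do not test equal responses. The day 15 count was 1899 without T47D day 15 replicate 3. G0S2 rose more in T47D, with a difference of 4.81 (SE 0.383) at day 3 and 5.04 (SE 0.383) at day 15 in log2 fold, which follows from its lower control level there.

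Among genes with mean log2 CPM of 1 or more in both lines, the most positive differences at day 3 besides G0S2 were in interferon-stimulated genes: IFI27 5.49 (SE 0.223), IFI44 4.99 (SE 0.266), IFIT1 4.65 (SE 0.0752) and OAS2 4.64 (SE 0.0968). In MDA-MB-231 these genes changed by 0.09, 0.10, 0.01 and 0.06 and were not called. Of 46 interferon genes measured in both lines 44 were more positive in T47D, with a median difference of 2.36 (camera adjusted p = 1.14e-11 with an estimated correlation), and of 18 antigen presentation genes 14 were (adjusted p = 0.000302). The most negative differences were in MPPE1 (-0.69, SE 0.116), GPNMB (-0.64, SE 0.0969), FBXO32, a ubiquitin ligase gene (-0.61, SE 0.0574), GARS1-DT (-0.56, SE 0.146) and SHISA2 (-0.55, SE 0.129). MPPE1 rose in MDA-MB-231 (0.73) and was not called in T47D (0.03), while GPNMB and FBXO32 fell in T47D (-0.35 and -0.45) and were not called in MDA-MB-231 (0.29 and 0.16). Cholesterol synthesis was more negative in T47D (6 of 24 genes, adjusted p = 0.000302), as were fatty acid synthesis (2 of 11 genes, 0.00609), hypoxia (3 of 17, 0.00905), ATF4 targets (2 of 25, 0.0199) and ER chaperones (2 of 18, 0.0199), and NF-kB and cytokine genes were more positive (4 of 13, 0.00104), each with an estimated correlation. The difference in SHISA2 was not called without MDA-MB-231 control replicates 1 or 2 (adjusted p = 0.0592 and 0.0579), MDA-MB-231 day 3 replicates 2 or 3 (0.0562 and 0.0609), T47D control replicate 1 (0.0696) or T47D day 3 replicate 2 (0.0556). That in GARS1-DT was not called with the replicate number as a block (0.0698). Nor was it without MDA-MB-231 control replicates 1 or 2 (0.139 and 0.0957), MDA-MB-231 day 3 replicates 1 or 2 (0.0602 and 0.129), T47D control replicates 1, 2 or 3 (0.0741, 0.0726 and 0.0993) or T47D day 3 replicates 1, 2 or 3 (0.082, 0.104 and 0.0712).

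Among the same genes at day 15 the most positive differences besides G0S2 were in TES (4.72, SE 0.0735), IFI44 (4.61, SE 0.266), IFI27 (4.32, SE 0.223) and OAS2 (2.75, SE 0.0968). TES was not called in MDA-MB-231 (0.006). The most negative were in SHISA2 (-1.56, SE 0.129), KITLG (-1.40, SE 0.0678), INHBA (-1.35, SE 0.122), EMP1 (-1.14, SE 0.118) and ANXA3 (-1.12, SE 0.0727), of which SHISA2 and EMP1 rose in MDA-MB-231 (0.19 and 0.11) and fell in T47D (-1.37 and -1.03). Of 46 interferon genes 43 were more positive in T47D (median difference 1.27, camera adjusted p = 1.7e-09 with an estimated correlation), and of 18 antigen presentation genes 12 (0.00264). Replication-dependent histones, which track RNA quality, were also more positive in T47D, in 2 of 7 genes at day 3 (adjusted p = 0.0112, and 0.156 with an estimated correlation) and 3 of 7 at day 15 (0.00584 and 0.127), with a median difference of 0.18 and 0.30. Of 25 ATF4 targets 12 were more negative in T47D (0.00524), as were 5 of 22 fatty acid oxidation genes, with 1 more positive (0.0309), and 3 of 4 MDA-MB-231 identity genes (0.0199). NF-kB and cytokine genes were more positive (5 of 13, with 2 more negative, 0.013).

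The rise of the interferon list in induced T47D cells was weighed against 3 technical explanations. Library scaling or a few abundant genes is argued against, since the day 3 median was 2.47 after quantile normalization, which put the median of all genes at -0.008. RNA of MDA-MB-231 cells in the T47D libraries is argued against as well: for the median member the rise would need a share of 102.9%, which would raise the 50 genes highest in MDA-MB-231 by a median of 7.42, and their median was 0.03 (SE 0.146). Doxycycline or the vector in place of G0S2 stays open: MDA-MB-231 at the same dose had a list median of 0.02, but that line can differ in its response, and no induced cells without the G0S2 gene were analysed here. A biological explanation, that G0S2 itself may start an interferon response in T47D, is a hypothesis. This design cannot separate it from doxycycline, the vector or time in culture.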

How the results depend on the processing

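Voom on the recovered reads, the GC correction and the omission of T47D day 15 replicate 2 outside its comparisons were chosen after the data were seen; the other settings were planned. No gene called both as reported and in another setting had opposite signs, in any of the 6 comparisons. Counts of called genes are given in the order MDA-MB-231 day 3, day 15 and day 15 against day 3, then T47D in the same order (253, 1173, 763, 277, 1659 and 824 as reported). With quantile normalization (280, 1180, 648, 275, 1572 and 812), the stricter filter (257, 1232, 800, 258, 1594 and 777) and voom (268, 1098, 662, 275, 1650 and 815) each count stayed within 1.5 times. Without trend and robust moderation, 63, 232 and 32 genes (6 higher, 26 lower) were called in MDA-MB-231, and 549 in T47D day 15 against day 3. With only the compared groups the counts were 476 and 776 in MDA-MB-231 at days 3 and 15, and 921 (389 higher, 532 lower), 996 and 463 in T47D. With the GC correction they were 539 (262 higher, 277 lower), 2685 and 1538 in T47D. A further 2-fold threshold left 4, 10, 3, 79, 111 and 64, because most called changes were smaller than that. Except for the 2-fold threshold, the cause was not tested.

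Replicate numbers were not taken to pair the samples, since the labels give no shared source. Correlations between libraries of the same number lay between -0.04 and 0.33 in MDA-MB-231, 8 of 9 of them positive, and between -0.51 and 0.09 in T47D, 3 of 9 positive. In 4 and 1 of these 9 pairs the correlation was above that of either library with the other numbers. Pairing in MDA-MB-231 is thus not excluded. With the number as a block, 637, 2273 and 1788 genes were called in MDA-MB-231, and 511 in T47D day 15 against day 3. Of the list results 127 stayed, 2 became called and 1 was lost with the block. The shared rises and falls numbered 147 and 179 in MDA-MB-231, and the shared falls 47 in T47D. The cause was not tested.

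Leaving out 1 library at a time, the counts ranged from 119 to 259, 457 to 1897 and 124 to 1664 in MDA-MB-231, and from 182 to 746, 930 to 3705 and 403 to 2604 in T47D. An omission leaves 2 libraries in a group, and the fit pools their spread with that of the other groups. Genes called at both times ranged from 22 to 77 (higher) and 49 to 111 (lower) in MDA-MB-231, and from 107 to 231 and 34 to 284 in T47D. The differences between lines ranged from 232 to 314 at day 3 and 860 to 1899 at day 15, and with a 2-fold threshold they numbered 72 and 71. Without T47D day 15 replicate 2, 14 lists were called in T47D at both day 3 and day 15. Without trend and robust moderation, 16 genes were higher and 24 lower at both times in MDA-MB-231, and 43 lower in T47D. For the T47D overlap of day 3 and day 15 responses, lower, the count was 210 with only the compared groups and 215 with the GC correction. The cause was not tested.

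With an estimated correlation, 7, 2, 3 and 3 lists were called at days 3 and 15 in MDA-MB-231 and T47D, where 13, 9, 14 and 12 were called with the preset one, because the estimate allows for correlated members. With the GC correction 115 list results stayed, 5 became called, 5 were lost and 1 changed direction: glycolysis in MDA-MB-231 at day 15, which was higher with an adjusted p of 0.0421. The cause was not tested. With quantile normalization 120 stayed, 2 became called and 8 were lost, and with voom 127 stayed and 3 became called.

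Of 263 named gene results, 133 kept their direction and call in every setting, 116 lost the call in at least 1, 4 became called in at least 1 and 10 changed sign. Besides omissions, losses were most frequent without trend and robust moderation (101 results), with only the compared groups (35) and with the GC correction (26). Those that changed sign were panel genes that were not called. With the GC correction in MDA-MB-231 at day 15, MYC was at 0.052 and CCND1 at 0.072. With quantile normalization in T47D at day 3, ESR1 was at 0.003 and CDH1 at 0.011. Leaving out 1 library at a time in T47D, the values at day 3 ranged from -0.021 to 0.056 for MYC, -0.014 to 0.001 for CDH1 and -0.042 to 0.032 for PNPLA2. At day 15 they ranged from -0.038 to 0.001 for GREB1, -0.043 to 0.028 for MYC, -0.008 to 0.190 for PNPLA2 and -0.038 to 0.020 for PLIN2. The cause was not tested. Of 20 named differences between lines, 18 held in every setting. No filter, another pseudocount and other count models were not run, since all listed genes are tested as deposited and the values are log2. At the depth of 37 to 52.4 M reads, the test on simulated reads recovered 48% to 60% of changes of 1.2-fold within a line, so small changes are missed.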

Other observations

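The tests on the neighbours of single genes, on the time course of the interferon list and on T47D day 15 replicate 2 were chosen after the result was seen; the splits of the libraries were planned.

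Outside the interferon and other immune lists, and besides G0S2 and unnamed loci, 14 genes in T47D were called at both times with a log2 fold of 1 or more at day 3 and a mean log2 CPM of 1 or more. Their names were chosen after their values were seen. The fixed interferon list does not hold every gene that responds to interferon, so these 14 are not a set free of interferon-stimulated genes. Most were called lower at day 15 than at day 3, among them DDX60L (3.02 at day 3, 1.44 at day 15), LAMP3 (2.07 and 1.03), PCDH20 (2.01 and 0.43), TRANK1 (1.56 and 0.67), TRIM21 (1.38 and 0.77) and SP100 (1.21 and 0.64). The fold of ADAM9 was 1.04 and 1.01, and its change from day 3 to day 15 was not called (adjusted p = 0.713). TES (4.34 and 4.73), SLC25A36 (1.48 and 1.67) and CUX2 (1.07 and 1.92) rose further from day 3 to day 15. In MDA-MB-231 at day 3 TES was not called (-0.03, adjusted p = 0.695) and SLC25A36 rose by 0.25 (adjusted p = 4.65e-05).

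The 3 rises whose day 15 fold was no lower than at day 3 were weighed against 2 explanations. An activation of the chromosomal neighbourhood is argued against: of the 5 nearest protein-coding genes on each side, 19 were measured and 0 were called higher at day 3 by limma, with a median of -0.04. At day 15, 2 of the 19 were called higher, CLSTN2 beside SLC25A36 (0.45) and FOXP2 beside TES (0.45), while MET beside TES fell by 1.40. The time course of the interferon list stays open: 3 of 14 rises outside the lists had a day 15 fold no lower than at day 3, against 0 of 38 interferon genes under the same selection (Fisher's exact p = 0.016, two-sided; genes are not independent replicates), but these 3 genes prompted the test, so it decides nothing. The same holds for an earlier one, the smallest change from day 3 to day 15 among the 3 genes (0.19, in SLC25A36). With a decline counted only where it was called, ADAM9 and IFI44 also count as not declining. An insertion of the introduced construct at one of the genes themselves stays open, since values per gene do not show it. No biological explanation was tested.

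T47D day 15 replicate 2 lay apart from its group, with an SD of its deviation across genes of 0.186, against 0.0687 to 0.146 in the other 17 libraries. A difference in depth is argued against, since its 45 M reads lie inside the range of the other T47D libraries (40.1 to 51). A mislabelled library of another group is argued against, since its interferon mean was 3.53 in log2 CPM, against 3.56 and 3.53 in the other day 15 libraries, 4.66 to 4.67 at day 3 and 2.01 to 2.07 in control. GC content bias stays open: the deviation correlated with GC content at 0.651, and a GC correction removed 46.1% of its variance and left an SD of 0.136. The correlation was -0.73 for replicate 3, whose comparison includes replicate 2, so the 2 cannot be told apart by this value. No biological explanation was tested.

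Within 1 line, 6 libraries of 2 groups can be split in only 10 ways, too few for a share under 0.05. The real split alone gave as many genes (1 of 10) in each of the 6 comparisons. In MDA-MB-231 it called 253 genes at day 3, 1173 at day 15 and 763 for day 15 against day 3, and the highest of the other splits called 0, 134 and 17. In T47D it called 277, 1659 and 824, and the highest of the others called 0, 0 and 1. For lists, adjusted within the comparison, it called 13 and 9 in MDA-MB-231 and 15 and 12 in T47D at days 3 and 15. The others called at most 10, 7, 7 and 10 (median 5, 4, 3 and 5), so 1 of 10 called as many. The preset correlation thus called lists under mixed labels too.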
